A study of Drosophila melanogaster with 15 samples.

How the data were processed

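The values are intensities on a linear scale, as deposited, 1 signal for each of 18952 probe sets on each of 15 arrays. Per the submitters' notes, the authors computed and scaled these intensities with MAS5, and the notes also name the Affymetrix Expression Console and the Transcriptome Analysis Console. Their scaling was kept. The 183 probe sets that serve as array controls were set aside, leaving 18769. Signals were put on a log2 scale after adding 16. A probe set was kept where at least 3 of the 15 arrays exceeded that array's own median, which left 10340. The signal's distance from background and the number of arrays limit the precision.

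All 15 arrays went into 1 limma fit with 5 group means (lmFit, then eBayes with an intensity trend), so that the groups shared 1 estimate of the spread. The labels number the arrays of each group but do not say what a number shares. Deviations from the group means correlated at 0.167 to 0.852 in all 18 pairs of same-numbered arrays among control, ND-75, UQCR-14 and COX5B RNAi, and at -0.362 to 0.149 in the 12 pairs with ATPsynCf6 RNAi. These values show a deviation shared by the arrays numbered 3 of the first 4 groups (0.595 to 0.852) and not by ATPsynCf6 RNAi. Deviations within a group cancel, so this alone would make their other same-numbered arrays correlate. Whether the other numbers pair arrays as well was therefore not settled. The replicate number was fitted as a block only over all 15 arrays without weights, and results are given where it changed a call there. The fits with array weights or with several arrays left out, described below, were not run with this block. Their calls therefore do not allow for a pairing of same-numbered arrays. Tests were two-sided. Benjamini-Hochberg adjustment ran over the kept probe sets of each contrast, and adjusted p under 0.05 was the threshold. The contrasts were each RNAi group against control, the mean of the 4 RNAi groups against control, a moderated F test of equality among the 4 RNAi groups, and the 6 pairs of RNAi groups. Changes are log2 fold changes with limma's standard error (SE). Signals are given per array, and every group had 3 arrays. An exact permutation test of 3 arrays against 3 cannot give a p under 0.1, so none was run on single genes.

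Probe sets were matched to genes with the annotation of the array. Of the 18769 probe sets, 13647 had exactly 1 gene, 402 had several and 4720 were not listed. Among those kept, the numbers were 8695, 256 and 1389. Probe sets without a gene symbol are named by their identifier. Gene lists, 48 in number, were written from general knowledge of fly genes. Of their 1017 symbols, 996 matched the annotation. The lists of salivary glue, fat body and muscle genes hold markers of other tissues that a dissected nervous system can carry. The 43 lists with at least 4 measured members were tested with limma's camera at a preset correlation of 0.01, on 1 probe set per gene (the brightest) over 7948 genes, with adjustment over the lists. Camera was also run with the correlation estimated from the data. Members of a list were counted when they passed the test over all probe sets, and again adjusted over the list alone.

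The groups, the tests, the lists, the first set of other settings and the rule for naming genes were fixed before the data were examined. The rule names the 4 targeted genes. For each RNAi group it names up to 6 genes with the largest rise and up to 6 with the largest fall that passed the test, had 1 gene symbol and had all 3 arrays on the same side of all 3 control arrays. It also names up to 10 genes called in the same direction in all 4 RNAi groups, and up to 4 members of each described list. It prescribes the brightest probe set of a gene. That was not followed for genes whose called probe set was another one, and these are pointed out. Array weights (limma's arrayWeights) were among those settings. Applying the naming rule to the array-weighted fit was decided after the data were seen. A fit of the 10 arrays left without the 5 of low upper quartile was also added after the data were seen, and list members beyond 4 were chosen after their values were seen. In the 10-array fit the COX5B group had 1 array, which was assumed to vary like the other groups.

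Recovery was tested on simulated arrays that varied independently, with the uneven spread between arrays that the array-weighted fit had estimated. This spread favours array weights and the 10 arrays. Of 200 probe sets changed by 1 in the UQCR-14 contrast, 0 were called without weights, 138 (69%) with array weights and 108 (54%) in the 10 arrays. At a change of 2 the numbers were 42 (21%), 199 (99.5%) and 198 (99%). The 10-array fit then made 61 and 57 false calls in the unchanged COX5B group of 1 array. Array weights made 8 and 12 false calls in the UQCR-14 contrast. Same-numbered arrays of 4 groups deviated together in the real data, so false calls there may be more. With an even spread, 0 of the 200 were called in each of the 3 fits at a change of 1. At a change of 2, 39 were called without weights, 39 with them and 0 in the 10 arrays. A simulated shift of 1 in 1 list gave it camera's adjusted p = 1.40e-09 without weights and 5.91e-35 with them, and 0 of 42 other lists were called. The simulated genes varied independently, so this does not measure false calls of lists whose genes are correlated. In the real arrays, other splits of 3 against 3 called up to 16 lists. Versions were R 4.3.3, limma 3.58.1, statmod 1.5.0, jsonlite 2.0.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.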

Results

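Transcript levels in the whole central nervous system of late L3 Drosophila larvae were measured on Affymetrix expression arrays. There were 5 groups of 3 arrays, 15 arrays in all. In each group the driver nSyb-Gal4, which is active in neurons, was present, and the control larvae carried it without an RNAi construct. The other 4 groups carried RNAi constructs against 1 subunit each of the respiratory chain or the ATP synthase. These were ND-75 of complex I, UQCR-14 of complex III, COX5B of complex IV and ATPsynCf6 of the ATP synthase. Each sample pooled 15 larvae reared at 25 °C, and 10 ng of RNA was amplified. The comparisons ask which transcripts of the nervous system respond when neurons lose parts of oxidative phosphorylation, and whether the response depends on the complex. No group carried an RNAi construct against an unrelated gene. Each target had a single RNAi line, numbered 33910, 109542, 105769 and 107826 in the order above. Differences between groups therefore cannot be told apart from differences between lines.

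Median signals ran from 22.7 to 63.2, and 5 arrays stood apart from the rest in the shape of their signal distribution. Their upper quartiles were 462 (control 3), 480 (ND-75 RNAi 3), 356 (UQCR-14 RNAi 3), 477 (COX5B RNAi 3) and 167 (COX5B RNAi 1). The other 10 arrays lay between 557 and 646. Across probe sets, the other 10 arrays correlated with each other at 0.969 to 0.990. The 4 of replicate 3 correlated among themselves at 0.915 to 0.969 and with those 10 at 0.774 to 0.927. COX5B RNAi 1 reached 0.490 to 0.732 with the other arrays. The ratio of 3' to 5' actin signal was 70.1 in COX5B RNAi 1, 37.4 in ND-75 RNAi 2 and 20.1 in ND-75 RNAi 3. It was 3.17 to 3.58 in the replicate 3 arrays of control, UQCR-14 RNAi and COX5B RNAi, and 2.94 to 5.03 in the remaining 9. Each comparison was therefore made over all 15 arrays, with array weights, and over the 10 arrays. The weights ran from 0.0266 for COX5B RNAi 1 to 5.21 for control 1. They were 0.297 or less in the 5 arrays and 1.01 or more in the 10. The fit with weights and that of the 10 arrays thus rest largely on the same arrays. Calls made in both are therefore no independent check of each other. The median change of all kept probe sets was 0.00 in ND-75 RNAi, -0.07 in UQCR-14 RNAi, -0.32 in COX5B RNAi and 0.07 in ATPsynCf6 RNAi. Centring each array on its median moved these to -0.11, -0.29, -0.31 and 0.09, and quantile normalization moved the COX5B value to -0.07.

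**Figure D1:**
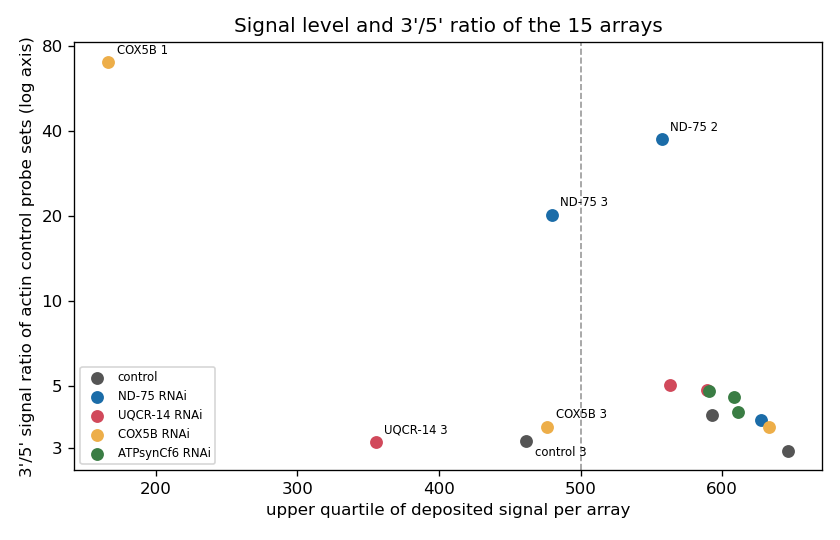
Upper quartile of the signal (linear axis) against the ratio of 3' to 5' actin signal (log axis) for each of the 15 arrays, coloured by group, with a dashed line at an upper quartile of 500. The 5 arrays under the line had upper quartiles of 167 to 480, and the other 10 had 557 to 646.

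Over 15 arrays, with array weights and over the 10 arrays, none of the 4 targeted genes passed the test in its own group. COX5B passed with quantile normalization and array weights together (-0.69, adjusted p = 0.00553). That setting was chosen after the results were seen, and it called far more probe sets in COX5B RNAi than these 3 fits did. ND-75 had the signals 305, 195 and 194 in its RNAi arrays and 335, 387 and 304 in control. Its mean on the log2 scale was 7.92 ± 0.35 (SD, n = 3) against 8.48 ± 0.17, a difference of -0.55 (SE 0.54, 95% interval -1.71 to 0.60). The signals of 195 and 194 came from ND-75 RNAi 2 and 3, whose actin ratios were 37.4 and 20.1, and the 305 of ND-75 RNAi 1 lay within the control range. Over the 10 arrays the difference was -0.53 with an interval of -0.98 to -0.07 (adjusted p = 0.275). COX5B had the signals 989, 1958 and 7716 in its RNAi arrays and 2725, 2952 and 8404 in control, where the highest in each group came from replicate 3. Its difference was -0.72 (SE 0.79, interval -2.40 to 0.96), and -0.53 (interval -1.02 to -0.04, adjusted p = 0.349) over the 10 arrays. Over 15 arrays it was -0.07 without COX5B RNAi 1, -1.54 without COX5B RNAi 3 and -0.20 without control 3. COX5B also stood at -0.47 in the ND-75 RNAi arrays over the 10 arrays. UQCR-14 had 7835, 6321 and 30487 in the arrays labelled UQCR-14 RNAi and 7959, 6616 and 20967 in control. Its difference was 0.15 (SE 0.85, interval -1.66 to 1.96), and -0.04 (interval -0.42 to 0.33) over the 10 arrays. ATPsynCf6, listed as ATPsynCF6, had 3585, 2828 and 3285 in the arrays labelled ATPsynCf6 RNAi and 3108, 3003 and 3579 in control. Its mean was 11.66 ± 0.17 against 11.66 ± 0.13 (SD, n = 3), and its interval was -0.87 to 0.87, or -0.20 to 0.35 over the 10 arrays. A loss of the transcript was thus not established in any of the 4 RNAi groups in these 3 fits. For UQCR-14 and ATPsynCf6 the differences over the 10 arrays, -0.04 and 0.07, also lay close to control. All groups are named by their labels.

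**Figure D2:**
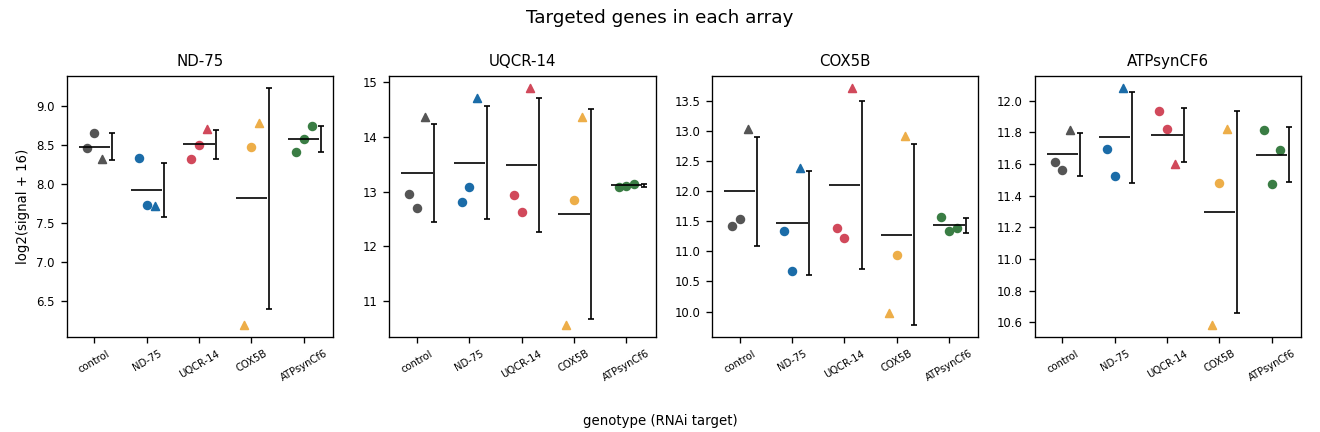
Levels of the 4 targeted genes as log2 of signal plus 16 in each of the 15 arrays, by group, with a line at the group mean and a bar for 1 SD. Triangles are the 5 arrays with an upper quartile under 500. UQCR-14 RNAi and ATPsynCf6 RNAi arrays overlapped the control arrays for their own gene.

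The ND-75 RNAi arrays had a few strong rises, among them those of a detoxification gene and a pigmentation gene. The latter, y, is on the written list of transgene and background markers. Whether the RNAi line carries such a marker was not tested. Cyp6a17, a cytochrome P450 (probe set 1628052_at), rose from control signals of 0.71 to 4.10 to signals of 445 to 509. With the 16 added to signals the change was 4.76 (SE 0.51, adjusted p = 0.000686), but control signals this close to background give no exact size, and it ran from 3.05 to 7.23 over 17 other settings. The gene y, which acts in cuticle pigmentation (1633285_at), rose from control signals of 54.1 to 63.1 to signals of 947 to 1723, a change of 4.24 (SE 0.65, adjusted p = 0.0177). CG15784 (1640884_at) rose from control signals of 65.1 to 77.1 to signals of 927 to 1414, by 3.72 (SE 0.45, adjusted p = 0.00158), and CG43117 rose by 2.28 (SE 0.38, adjusted p = 0.0325). RFeSP, the iron-sulphur subunit of complex III, fell by 2.34 (SE 0.36, adjusted p = 0.0181) at its dimmer probe set, 1641174_at, while the brighter probe set stood at -0.57. Its signals of 11.4 to 24.7 in ND-75 RNAi lay under the array medians, so the fall has no exact size, and it ran from -3.14 to -1.39 over 16 other settings. The unnamed probe sets 1640448_x_at and 1634666_at rose by 2.98 and 2.67 from control signals of 16.3 to 25.6 and 5.67 to 10.2, also under the medians, which makes 6 that rose and 1 that fell over 15 arrays (155 at an unadjusted p under 0.05). Cyp6a17 and CG15784 were called in all 15 fits that left out 1 array. The call of y ended without ND-75 RNAi 1 (adjusted p = 0.136), ND-75 RNAi 2 (0.154), control 1 (0.0906), control 2 (0.112) or control 3 (0.0839), and that of RFeSP without any of the 3 ND-75 RNAi or 3 control arrays (0.0550 to 0.184). CG43117 kept its call in 4 of the 15 fits, with adjusted p of 0.0132 to 0.279. The count of 7 became 4 without ND-75 RNAi 1, ND-75 RNAi 2, control 1 or control 2, and 16 without COX5B RNAi 1.

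With array weights Arc1 and Oseg2 rose and Snap24 fell in ND-75 RNAi. In that fit 96 probe sets rose and 66 fell, and over the 10 arrays 93 rose and 82 fell, with 130 called in both with the same sign. The actin ratios of ND-75 RNAi 2 and 3 were 37.4 and 20.1, and leaving ND-75 RNAi 2 out of the 10 arrays moved the count from 175 to 96, with Arc1, Oseg2 and Snap24 still called. Arc1, which encodes a capsid-like protein of synapses, rose by 2.69 (SE 0.23, adjusted p = 1.17e-06) and by 1.84 at its other probe set. Oseg2, a gene of transport in cilia, rose by 2.37 (SE 0.24, adjusted p = 9.29e-06). Snap24, a SNARE protein of vesicle fusion, fell by 3.23 (SE 0.33, adjusted p = 7.92e-06). Control signals of Arc1 (2.70 to 9.21) and Oseg2 (4.53 to 9.95) lay under the array medians, so their rises have no exact size, and over 17 other settings they ran from 1.48 to 4.31 and from 1.22 to 3.58. Smaller falls were those of CG11349 (-1.70), CG33468 (-1.59), CG1299 (-1.53) and the transcription factor lola (-1.52, 1 of its 14 probe sets).

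The carbohydrate genes moved upward as a list in ND-75 RNAi. The 13 measured genes of glycolysis and lactate metabolism had adjusted p = 0.00503 over 15 arrays, with 0 members called, 0 adjusted over the list alone, and adjusted p = 0.975 with an estimated correlation. The call also ended without the filter on dim probe sets (0.183). It was the 1 list called there, where the fit with the replicate number as a block called 2. With array weights the list had adjusted p = 0.000313, and adjusted p = 0.0980 with an estimated correlation. Tret1-1, a trehalose transporter, rose by 1.83, the hexokinase Hex-A by 1.03 and the aldolase Ald1 by 0.80, while 10 members were not called, and 3 rose adjusted over the list alone. Of 28 genes of the ATF4 and integrated stress response, Pepck2 alone rose (1.06), and the list had adjusted p = 0.0457 with array weights (adjusted p = 0.709 with an estimated correlation). In that list 2 genes rose and 1 fell adjusted over the list alone. The 8 salivary glue genes were called upward with array weights (adjusted p = 0.0457; adjusted p = 0.958 with an estimated correlation) without a called member, while 2 rose adjusted over the list alone, and not over the 10 arrays (adjusted p = 0.427). Over 15 arrays camera put them downward (adjusted p = 0.792), although their median change was 0.23.

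The arrays labelled UQCR-14 RNAi were marked by a related pair of cytochrome P450 genes and a heat shock cognate. Cyp4p2 (1640566_at) rose to signals of 473 to 583, where no other array exceeded 44.3, a change of 4.33 (SE 0.40, adjusted p = 0.000174). Cyp4p1 (1638053_at) rose by 2.84 (SE 0.34, adjusted p = 0.00285), with signals of 102 to 207 against 2.82 to 15.5 in control. Hsc70-2 (1636055_at), a chaperone, rose by 3.92 (SE 0.52, adjusted p = 0.00602), with signals of 424 to 479 against 7.14 to 32.3. With such low control signals these 3 changes depended on the setting, from 2.97 to 5.55, 1.63 to 4.22 and 2.70 to 4.95. Zip102B (1626088_at), of a zinc transporter family, fell by 2.60 (SE 0.43, adjusted p = 0.0467), with signals of 14.8 to 70.2 against 190 to 394. RFeSP fell by 2.26 (SE 0.36, adjusted p = 0.0393) at its dimmer probe set, while the brighter stood at -0.31. Its signals were 6.80 to 26.2, under the array medians, and the fall ran from -3.07 to -1.35 over 16 other settings, that of Zip102B from -3.12 to -1.82 over 17. In all, 3 probe sets rose and 2 fell (229 at an unadjusted p under 0.05). With the replicate number as a block 3 were called, and Zip102B and RFeSP were not (adjusted p = 0.0513 each). Cyp4p2 and Cyp4p1 were called in all 15 fits that left out 1 array. Hsc70-2 was not called without UQCR-14 RNAi 1 (adjusted p = 0.0519), control 1 (0.0681) or control 2 (0.0780). RFeSP kept its call without COX5B RNAi 1 or COX5B RNAi 3 alone (0.00897 to 0.310 over the 15), and Zip102B without UQCR-14 RNAi 3, COX5B RNAi 1 or COX5B RNAi 3 alone (0.0185 to 0.536). The count of 5 became 3 without any array of ATPsynCf6 RNAi or ND-75 RNAi, UQCR-14 RNAi 2 or COX5B RNAi 2. It became 2 without UQCR-14 RNAi 1, control 1 or control 2, and 12 without COX5B RNAi 1.

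With array weights the UQCR-14 RNAi arrays had 282 rises and 180 falls, and 248 and 227 over the 10 arrays (309 in both with the same sign). Of the 10 splits of the UQCR-14 RNAi and control arrays, 6, the real one included, called 462 or more with array weights. In the real comparison with array weights, Tret1-1 rose by 2.39 (SE 0.26, adjusted p = 2.14e-05). Inos, which makes inositol phosphate, rose by 2.16 (SE 0.28, adjusted p = 0.000135), and CdGAPr, a GTPase activator, by 2.12 (SE 0.21, adjusted p = 1.03e-05). CG6912 fell by 3.19 (SE 0.22, adjusted p = 9.78e-08), Snap24 by 3.10 (SE 0.33, adjusted p = 1.78e-05), Phyhd1 by 2.71 (SE 0.26, adjusted p = 6.99e-06) and CG18545 by 2.47 (SE 0.34, adjusted p = 0.000313). Signals of Phyhd1 (6.77 to 34.6) and CG18545 (2.90 to 34.5) in these arrays lay under the medians, and over 17 other settings the falls ran from -3.31 to -1.32 and from -2.60 to -0.86. Glycolysis and lactate genes were up as a list over 15 arrays (adjusted p = 0.00542; adjusted p = 0.333 with an estimated correlation) with 0 of 13 members called, also adjusted over the list alone. The call also ended without the filter (0.168), with all probe sets of each gene (0.0591) and with quantile normalization and weights (0.0596). With array weights Tret1-1 and Ald1 (0.88) rose, 11 were not called, 4 rose adjusted over the list alone, and the list had adjusted p = 0.00238 (adjusted p = 0.246 with an estimated correlation). Over 15 arrays Ald1 stood at 0.46, and at 0.24, 0.25 and 0.89 without UQCR-14 RNAi 1, 2 and 3. The 18 detoxification P450s were up as a list (adjusted p = 1.03e-06; adjusted p = 0.296 with an estimated correlation), with Cyp4p2 and Cyp4p1 called, 2 adjusted over the list alone and 16 not called. With array weights Cyp9b2 (1.05) rose as well, but over the 10 arrays neither it (adjusted p = 0.0987) nor the list (0.167) was called. The list was also not called without UQCR-14 RNAi 3 over 15 arrays (adjusted p = 0.0551) or with quantile normalization and weights (0.895).

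Lists of salivary glue, fat body and muscle genes were up in the UQCR-14 RNAi arrays at the preset correlation, and none of them with an estimated one. These lists mark other tissues, and whether the dissections carried different amounts of them was not tested. The 8 salivary glue genes were up over 15 arrays (adjusted p = 8.67e-10; adjusted p = 0.296 with an estimated correlation) with 0 members called, also adjusted over the list alone. With array weights Sgs5 rose by 2.62, Sgs8 by 2.11, Sgs4 by 2.07 and Sgs7 by 2.03, 4 were not called, 6 rose adjusted over the list alone, and the list had adjusted p = 3.87e-06 (adjusted p = 0.494 with an estimated correlation). Over 15 arrays, leaving out control 1 or control 3 gave 0.79 or 3.11 for Sgs8, 0.82 or 2.91 for Sgs7 and 1.12 or 2.95 for Sgs5, and Sgs4 ran from 0.94 without UQCR-14 RNAi 1 to 1.99 without UQCR-14 RNAi 3. Without UQCR-14 RNAi 3, Sgs7 stood at 1.07 and Sgs8 at 0.98. The 10 fat body genes (adjusted p = 0.00969; adjusted p = 0.296 with an estimated correlation) and the 14 muscle genes (adjusted p = 0.0170; adjusted p = 0.333 with an estimated correlation) were up over 15 arrays with 0 members called, also adjusted over the list alone. With array weights Desat1 (0.67) rose in the first, 1 adjusted over the list alone. Act79B (1.10) rose in the second, where 6 rose and 1 fell adjusted over the list alone. Act79B (adjusted p = 0.176) and the muscle list (0.0796) were not called over the 10 arrays, and over 15 Act79B moved from 0.66 to 0.32 without control 1. The fat body list was not called without UQCR-14 RNAi 3 (0.385), control 1 (0.119) or control 2 (0.249), nor the muscle list without UQCR-14 RNAi 2 (0.289), UQCR-14 RNAi 3 (0.198) or control 1 (0.381). Both calls also ended without the filter (fat body 0.158, muscle 0.320) and with quantile normalization, alone (0.159 and 0.171), with the term for 4 arrays (0.0913 and 0.253), with weights (0.156 and 0.895) and without the 5 arrays (0.126 and 0.177). The 4 antimicrobial peptides had adjusted p = 0.0167 (adjusted p = 0.333 with an estimated correlation), 0 members called and 0 adjusted over the list alone. Their call ended without UQCR-14 RNAi 3 (0.766), COX5B RNAi 1 (0.0755), control 1 (0.126) or control 2 (0.331), without the filter (0.599) and with quantile normalization (0.171). The 29 cytosolic ribosomal proteins were up over 15 arrays (adjusted p = 1.88e-05; adjusted p = 0.993 with an estimated correlation) with 0 called, also adjusted over the list alone. Their direction turned with quantile normalization (adjusted p = 0.930), and without UQCR-14 RNAi 3 (0.145), and they were not called without control 2 (0.750). With array weights neither the peptides (0.344) nor these ribosomal proteins (0.135) were called. With array weights the 17 ecdysone response genes were up (adjusted p = 0.0332; adjusted p = 0.737 with an estimated correlation), and the nuclear receptors EcR (1.04) and Hr3 (1.11) rose, 2 adjusted over the list alone. Over 15 arrays EcR stood at 0.61, and at 0.92 without UQCR-14 RNAi 3, and Hr3 at 0.52, and at 0.14, 0.13 and 1.29 without UQCR-14 RNAi 1, 2 and 3 and 0.31 without control 3.

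COX5B RNAi had its strongest changes in genes that changed in other RNAi groups as well, such as the chaperone gene Hsc70-2, the transporter gene Tret1-1 and CG15784. They passed the test with array weights, where COX5B RNAi 2 held most of the weight of its group. Over 15 arrays limma called no probe set in COX5B RNAi, whose 3 arrays differed most from each other. At an unadjusted p under 0.05 there were 578, and 1 was called without UQCR-14 RNAi 3. RFeSP had the lowest adjusted p, 0.0704, at -2.43, with the brighter probe set at -1.48. With array weights 14 rose and 7 fell. The weights were 0.0266 for COX5B RNAi 1, 1.01 for COX5B RNAi 2 and 0.297 for COX5B RNAi 3. These changes thus rest largely on COX5B RNAi 2, the only COX5B RNAi array among the 10, so the 10 arrays are no independent check of them. Hsc70-2 rose by 3.08 (SE 0.39, adjusted p = 0.000724), CG12607 by 2.58 (SE 0.44, adjusted p = 0.0139), CG15784 by 2.32 (SE 0.32, adjusted p = 0.00199), Tret1-1 by 2.27 (SE 0.42, adjusted p = 0.0258) and CdGAPr by 2.19 (SE 0.34, adjusted p = 0.00776). CG9945 rose by 1.47, while its other probe set stood at -0.81. CG6912 fell by 3.21 (SE 0.36, adjusted p = 0.000533), Snap24 by 2.74 (SE 0.53, adjusted p = 0.0374) and RFeSP by 2.17 (SE 0.35, adjusted p = 0.00943). CG17816 (-2.18) and the kinase gene Slik (-1.86) fell at 1 probe set each, with their other probe sets at 0.48 and 0.24. Over 15 arrays CdGAPr stood at 3.07 and CG17816 at -2.60, and at 2.03 and -1.54 without COX5B RNAi 1. With any 1 array left out, CdGAPr ran up to 3.81 (COX5B RNAi 3), CG17816 down to -3.27 (control 3), Hsc70-2 from 1.73 (COX5B RNAi 2) to 2.80 (COX5B RNAi 1) and CG15784 from 1.34 to 2.02 (the same 2 arrays). Over 17 other settings Hsc70-2, with control signals near background, ran from 1.26 to 3.21, and over 16 CG12607 ran from 1.17 to 2.73 and RFeSP from -3.54 to -1.41.

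Genes of protein synthesis were lower as lists in COX5B RNAi over 15 arrays at the preset correlation, against a median change of -0.32 of all probe sets, and not with an estimated correlation. The 71 mitochondrial ribosomal proteins had adjusted p = 0.0116, the 18 cytosolic aminoacyl-tRNA synthetases 0.0362 and the 25 ribosome biogenesis genes 0.0379, all downward, and each had adjusted p = 0.975 with an estimated correlation. The muscle (0.0396) and ecdysone response lists (0.0486) were upward, with the same 0.975 at an estimated correlation. For each of these 5 lists 0 members were called, also adjusted over the list alone. Without COX5B RNAi 1 the adjusted p was 0.945 for the mitochondrial ribosomal list, which turned, and the synthetase and ecdysone lists, 0.288 for muscle and 0.0586 for ribosome biogenesis. Calls also ended without control 3 (mitochondrial ribosomal 0.747, ecdysone 0.158), control 1 (synthetases and ribosome biogenesis 0.0628, muscle 0.226) and control 2 (ribosome biogenesis and ecdysone 0.0579). They ended without COX5B RNAi 2 (mitochondrial ribosomal 0.101), COX5B RNAi 3 (ribosome biogenesis and muscle 0.0716) and UQCR-14 RNAi 3 (ribosome biogenesis, muscle and ecdysone 0.0504). The ecdysone list was not called without ND-75 RNAi 1 (0.0510) or ND-75 RNAi 3 (0.0532), nor with quantile normalization (0.0545). Without the filter muscle had 0.124 and ecdysone 0.119, and with all probe sets of each gene 0.163 and 0.0617, while ribosome biogenesis had 0.0514 with the term for 4 arrays. With array weights the mitochondrial ribosomal direction turned (adjusted p = 0.342), the synthetase (0.342), muscle (0.171) and ecdysone lists (0.764) were not called, ribosome biogenesis stayed down (adjusted p = 0.0187; adjusted p = 0.996 with an estimated correlation) with 0 members called, and EcR rose by 1.35 (over 15 arrays 2.15, and 1.07 and 2.78 without COX5B RNAi 1 and 3). Also with array weights, the glue genes (adjusted p = 0.0213; adjusted p = 0.996 with an estimated correlation) were up with 0 members called, and the glycolysis and lactate genes (adjusted p = 0.0492; adjusted p = 0.996 with an estimated correlation) with Tret1-1 alone, but neither was called over the 10 arrays (0.477 and 0.310). Adjusted over the list alone, 0 genes passed for ribosome biogenesis and glue and 1 for glycolysis.

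In the arrays labelled ATPsynCf6 RNAi, Hsc70-2 and CG5079 rose over 15 arrays. Hsc70-2 rose by 4.09 (SE 0.52, adjusted p = 0.00537), to signals of 484 to 575 (2.86 to 5.13 over 17 other settings), and CG5079 (1635613_at) by 2.58 (SE 0.32, adjusted p = 0.00537), with signals of 205 to 241 against 15.9 to 29.1 in control. These control signals lay under the array medians, so the rise of CG5079 has no exact size, and it ran from 1.69 to 3.19 over 17 other settings. These were the 2 called (134 at an unadjusted p under 0.05). Neither was called without ATPsynCf6 RNAi 1 (adjusted p = 0.0570), ATPsynCf6 RNAi 3 (0.0557), control 1 (0.0638) or control 2 (Hsc70-2 0.0723, CG5079 0.0519), which left a count of 0. The count was 7 without UQCR-14 RNAi 3 and 14 without COX5B RNAi 1. With array weights 422 rose and 293 fell, and 197 and 136 over the 10 arrays (313 in both with the same sign). CG15784 rose by 2.69 (SE 0.15, adjusted p = 2.06e-09), Tret1-1 by 2.56 (SE 0.20, adjusted p = 1.38e-07), the prolyl hydroxylase PH4alphaSG1 by 2.51 (SE 0.26, adjusted p = 3.64e-06) and Oseg2 by 2.33. Snap24 fell by 3.18 (SE 0.25, adjusted p = 1.75e-07), the glutamate receptor KaiR1D by 2.70 (SE 0.16, adjusted p = 5.61e-09) and CG6912 by 2.51 (SE 0.17, adjusted p = 1.99e-08). CG15919 (-2.32), CG18545 (-2.19) and CG11349 (-2.08) fell too. Control signals of PH4alphaSG1 (1.24 to 14.6) and Oseg2 (4.53 to 9.95) and the CG18545 signals of 2.17 to 21.9 in ATPsynCf6 RNAi lay under the medians, and these changes ran from 1.13 to 4.16, 1.29 to 3.70 and -2.96 to -0.94 over other settings.

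In ATPsynCf6 RNAi, 7 of 13 glycolysis and lactate genes rose with array weights. Besides Tret1-1 these were Hex-A (1.42), Ald1 (1.01), Pfk (0.72), Pgi (0.66), Treh (0.63) and Tpi (0.62), while 6 were not called and 8 rose adjusted over the list alone. Treh was not called over the 10 arrays (adjusted p = 0.0591), and over 15 Pgi moved from 0.95 to 0.61 without control 3. The list had adjusted p = 8.22e-09 (adjusted p = 0.00774 with an estimated correlation), and adjusted p = 0.0960 with an estimated correlation over the 10 arrays. Numbers of called members were not compared between RNAi groups, and the ATPsynCf6 RNAi arrays held weights of 3.82 to 4.78. Over 15 arrays the glycolysis list had adjusted p = 1.76e-05 (adjusted p = 0.202 with an estimated correlation) with 0 members called and 2 adjusted over the list alone. Genes of the ATF4 and integrated stress response were up over 15 arrays (adjusted p = 0.00131; adjusted p = 0.623 with an estimated correlation), with 0 of 28 called and 1 adjusted over the list alone. With array weights the list had adjusted p = 0.000969 (adjusted p = 0.266 with an estimated correlation), and 6 members rose, 7 adjusted over the list alone beside 2 that fell. They were Pepck1 (1.68), Gadd45 (1.05), the amino acid transporter JhI-21 (0.83), the asparagine synthetase AsnS (0.74), sbm (0.72) and CG10365 (0.71). The calls of Gadd45 (adjusted p = 0.170) and CG10365 (0.0799) ended over the 10 arrays.

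Some glutathione S-transferase genes rose in ATPsynCf6 RNAi with array weights, 8 of 25, among them GstE1 (1.86), GstD2 (1.79), GstE6 (0.97) and GstE3 (0.82), and GstZ2 fell (-0.50). Over 15 arrays GstE1 moved from 1.22 to 0.66 and GstE6 from 0.75 to 0.47 without control 1. Adjusted over the list alone 10 rose and 4 fell, and the list had adjusted p = 0.00601 (adjusted p = 0.724 with an estimated correlation), a direction that turned without the filter on dim probe sets (adjusted p = 0.782). Over the 10 arrays 3 of the 8 rose, while GstE6 (adjusted p = 0.116), GstE3 (0.120), GstE2 (0.171), GstO1 (0.221), GstE9 (0.210) and GstZ2 (0.132) were not called. Of 13 mitochondrial chaperones and proteases, Hsc70-5 (0.49) and Afg3l2 (0.48) rose with array weights, 5 adjusted over the list alone (adjusted p = 0.0104; adjusted p = 0.285 with an estimated correlation), but not over the 10 arrays (adjusted p = 0.0582 and 0.0717), where 0 members were called. Desat1 rose by 0.57 in the fat body list (adjusted p = 0.0314; adjusted p = 0.266 with an estimated correlation), where 2 rose adjusted over the list alone.

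The list of steroid synthesis genes of the ring gland, which is attached to the larval brain, was down in ATPsynCf6 RNAi over 15 arrays but not called with array weights or over the 10 arrays. With all 15 the 10 genes had adjusted p = 1.76e-05 (adjusted p = 0.202 with an estimated correlation), with 0 called and 1 fall adjusted over the list alone. With array weights spok (-1.68) and sad (-1.82) fell and EcR (0.52) rose, while the list was not called (adjusted p = 0.174). Neither spok (adjusted p = 0.120), sad (0.0981) nor the list (0.158) was called over the 10 arrays. Over 15 arrays the 27 complex I subunits (adjusted p = 0.000381; adjusted p = 0.768 with an estimated correlation), the mitochondrial ribosomal proteins (adjusted p = 0.000233; adjusted p = 0.768 with an estimated correlation), the cytosolic ribosomal proteins (adjusted p = 0.0231; adjusted p = 0.768 with an estimated correlation) and the glue genes (adjusted p = 0.000244; adjusted p = 0.623 with an estimated correlation) were down. In all of these 0 members were called, also adjusted over the list alone. Without control 3 the direction turned for complex I (0.998), mitochondrial ribosomal (0.741) and cytosolic ribosomal genes (0.0480), and the glue genes were not called (0.529). The cytosolic ribosomal list was not called without ATPsynCf6 RNAi 1 (0.159) or COX5B RNAi 1 (0.0834), without the filter (0.102), with quantile normalization (0.665) or with all probe sets of each gene (0.0624). The term for 4 arrays ended the calls of the complex I (0.284), mitochondrial ribosomal (0.0684) and glue genes (0.0684). With array weights complex I (0.824) and glue genes (0.652) were not called, and the ribosomal directions turned, for the mitochondrial (adjusted p = 0.577) and the cytosolic list (adjusted p = 0.174).

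**Figure D3:**
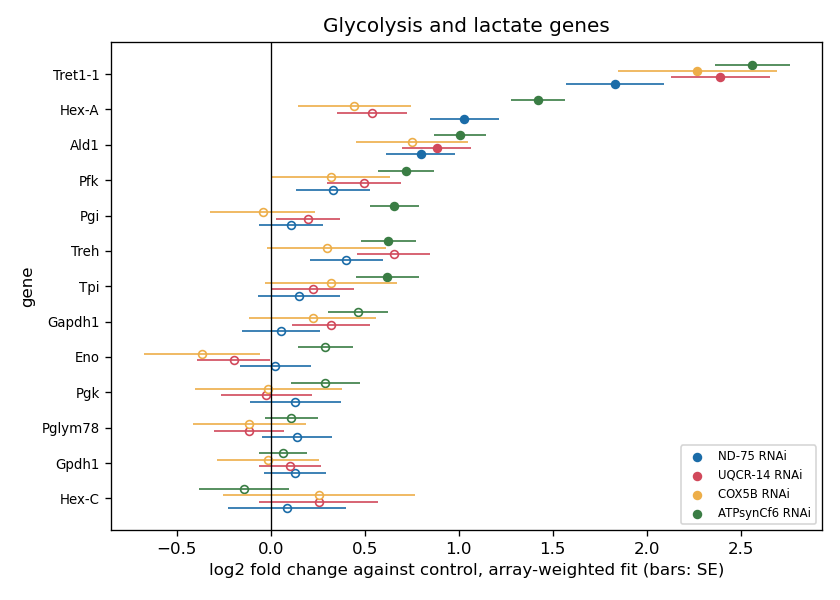
Array-weighted log2 fold changes (± SE) of the 13 measured glycolysis and lactate genes in each RNAi group against control, with filled points for genes that passed the test. Points filled in ATPsynCf6 RNAi are 7 of 13, and Tret1-1 is filled in all 4 RNAi groups.

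Hsc70-2, CG15784 and CG5079 rose and RFeSP fell in the mean of the 4 RNAi groups against control, which called 5 probe sets over 15 arrays (176 at an unadjusted p under 0.05). Hsc70-2 had a mean change of 2.70 (SE 0.41, adjusted p = 0.0231), CG15784 2.37 (SE 0.36) and CG5079 1.72 (SE 0.25). The unnamed 1635227_at had 2.31, and RFeSP fell by 2.19 (SE 0.29) at its dimmer probe set. Since control signals of Hsc70-2 and CG5079 and most RFeSP signals in the RNAi groups lay under the array medians, these 3 sizes are not exact. With array weights 227 rose and 186 fell, and 172 and 151 over the 10 arrays (258 in both with the same sign). The count of 5 became 1 without ATPsynCf6 RNAi 2 or 3, ND-75 RNAi 1, UQCR-14 RNAi 1 or 2, or control 3. It became 3 without ND-75 RNAi 2 or 3, 0 without control 1 or 2, and 11 without COX5B RNAi 1.

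No probe set was called in the same direction in all 4 RNAi groups over 15 arrays with limma, where single comparisons had 134 to 578 at an unadjusted p under 0.05. With array weights 8 rose and 3 fell in all 4, a count of 11 that 17 of 100 splits of the arrays reached, and over the 10 arrays 20 rose and 16 fell. CG15784 rose by 3.82 in ND-75, 1.87 in UQCR-14, 2.32 in COX5B and 2.69 in ATPsynCf6 RNAi. In the same order Tret1-1 rose by 1.83, 2.39, 2.27 and 2.56. GstD2 rose by 1.89, 1.83, 2.01 and 1.79, and Arc2, a relative of Arc1, by 2.34, 1.72, 1.81 and 1.98. Hsc70-2 rose by 1.03, 4.15, 3.08 and 4.35, the ND-75 value without a call over the 10 arrays (adjusted p = 0.243). RFeSP changed by -2.23, -2.05, -2.17 and -1.80, Snap24 by -3.23, -3.10, -2.74 and -3.18, and CG17816 by -1.17, -1.71, -2.18 and -0.94. For RFeSP and CG17816 these are values of 1 probe set each. In ND-75, UQCR-14 and COX5B RNAi the brighter RFeSP probe set fell less over 15 arrays. In COX5B RNAi the other CG17816 probe set stood above control. Leaving 1 array out of the 15 turned 2 of these 8 genes. Arc2 in COX5B RNAi, at 0.42 over 15 arrays, stood at -0.31 without COX5B RNAi 3, -0.09 without COX5B RNAi 2, 1.66 without COX5B RNAi 1, 0.21 without control 1 and 0.76 without control 3. CG17816 in ATPsynCf6 RNAi, at -0.29, stood at 0.07 without control 1, 0.01 without control 2, -0.96 without control 3 and -0.17 without ATPsynCf6 RNAi 2. In ND-75 RNAi CG17816 moved from -0.65 to -0.29, -0.34 and -1.32 without control 1, 2 and 3, and Hsc70-2 from 0.66 to 0.42 and 1.01 without ND-75 RNAi 1 and 2. In UQCR-14 RNAi CG17816 moved from -1.20 to -1.87 without control 3, and in COX5B RNAi from -2.60 to -1.54 without COX5B RNAi 1. UQCR-14 and ATPsynCf6 were not lower in their own arrays, so the 4 groups share RNAi labels rather than a measured loss of each target. RFeSP signals were 128 to 179 in control and 2.75 to 36.1 in the RNAi groups, at or under most array medians, so the size of its fall is not exact, and Snap24 signals 239 to 1346 and 35.4 to 168. With array weights the pairs of RNAi groups shared 8 to 112 rises and 3 to 85 falls. Independent lists would share 0.130 to 11.5 and 0.0447 to 5.10, which leaves out the shared controls, and simulated unchanged groups shared 0, which leaves out the effects. Neither is the overlap to be had without a shared response, and part of it may come from the shared controls.

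**Figure D4:**
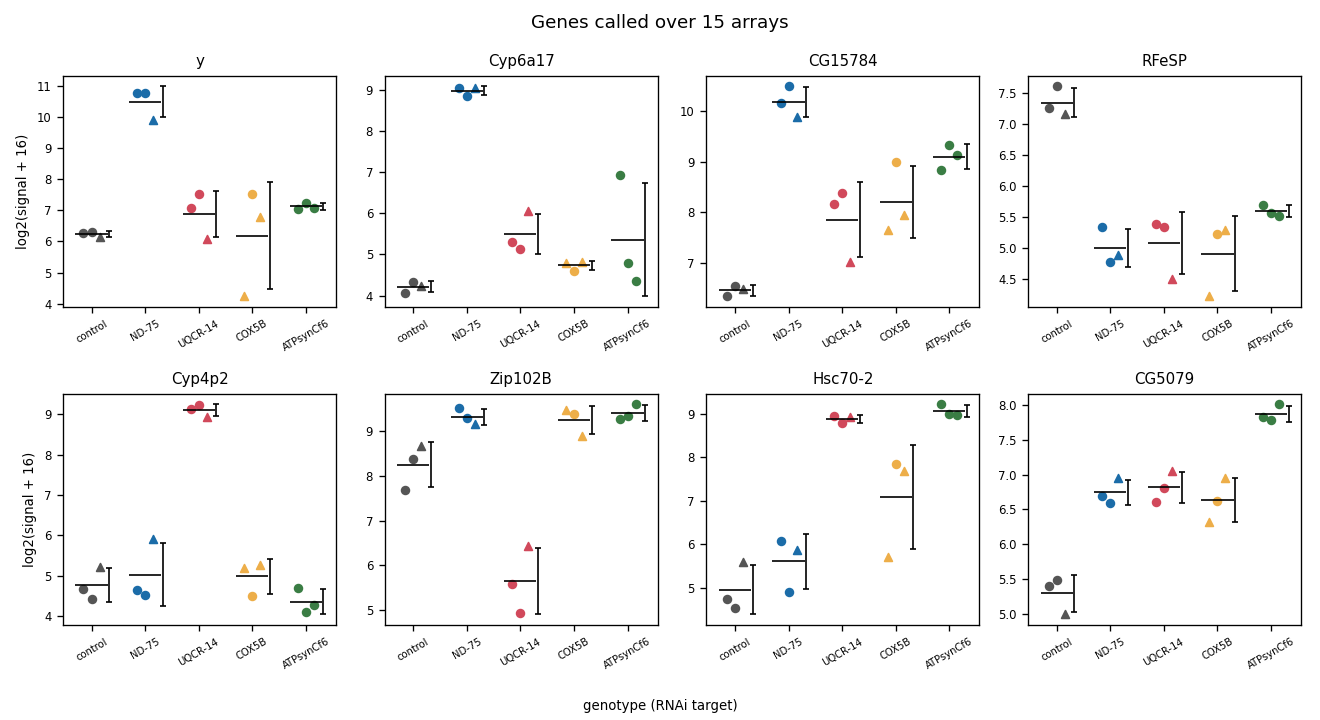
Levels of y, Cyp6a17, CG15784, RFeSP, Cyp4p2, Zip102B, Hsc70-2 and CG5079 as log2 of signal plus 16 in each of the 15 arrays, by group, with a line at the group mean and a bar for 1 SD. Triangles are the 5 arrays with an upper quartile under 500, and the Cyp4p2 signals of 473 to 583 are those of UQCR-14 RNAi.

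Apart from RFeSP, which fell at its dimmer probe set, subunits of the respiratory complexes on the lists did not pass the test. Among 27 complex I, 7 complex III, 8 complex IV and 12 ATP synthase subunits on the lists, 0 were called by limma in any of the 4 comparisons over 15 arrays, with array weights or over the 10 arrays. These counts take the brightest probe set of a gene, which for RFeSP is not the called one. Over the 10 arrays, with the deposited scaling, the complex I list was nevertheless down in ND-75 (adjusted p = 0.0196), UQCR-14 (0.0440) and COX5B RNAi (0.00638), with medians of -0.17, -0.18 and -0.16. With an estimated correlation the adjusted p was 0.705, 0.909 and 0.915, and 0 members fell adjusted over the list alone. At an unadjusted p under 0.05 each comparison had 134 to 578 probe sets over 15 arrays. Of the 43 lists, 24 were called in no RNAi group in any of the 3 fits.

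Cyp4p2, Cyp4p1 and Zip102B set UQCR-14 RNAi apart from the other RNAi groups, and Cyp6a17 set ND-75 RNAi apart. With a single RNAi line per target, such differences may come from the line as well as from the complex. The F test called 11 probe sets over 15 arrays, all of which were also called with array weights and over the 10 arrays. Cyp4p2 (adjusted p = 0.000148), Cyp4p1 (0.00122) and Zip102B (0.00122) differed between UQCR-14 RNAi and each of the other RNAi groups. Cyp6a17 (0.00311), 1634666_at (0.000847) and 1640448_x_at (0.00122) differed between ND-75 RNAi and each of the others. Hsc70-2 (0.0243) was lower in ND-75 RNAi than in UQCR-14 and ATPsynCf6 RNAi. Pepck1 (0.0112) was higher in ATPsynCf6 than in COX5B RNAi, y (0.0349) and CG43117 (0.0349) were higher in ND-75 than in COX5B RNAi, and CG18095 (0.0496) was higher in ATPsynCf6 than in ND-75 RNAi. With array weights Zip102B rose in ND-75 (1.46) and ATPsynCf6 RNAi (1.44) and fell in UQCR-14 RNAi (-2.80), and 281 probe sets differed, 455 over the 10 arrays. CG6912 and KaiR1D differed among the RNAi groups with array weights (adjusted p = 2.07e-06 and 2.10e-06), and Snap24 and Tret1-1 did not (0.987 and 0.408). Pairs of RNAi groups differed at 11 probe sets over 15 arrays, 468 with array weights and 747 over the 10 arrays. The F count became 6 without any array of ATPsynCf6 RNAi and 7 without any array of ND-75 RNAi, UQCR-14 RNAi 1 or control 1. The pairwise count became 7 without ND-75 RNAi 1 or 2 and 23 without COX5B RNAi 1.

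Fold changes of the RNAi groups correlated with each other in all 6 pairs. Across 10340 probe sets, which are not independent replicates, the mean correlation of the 6 pairs was 0.318 (0.215 to 0.450) over 15 arrays. Unchanged groups simulated against shared controls, which were simulated too, gave 0.384, and the covariance was lower than in them (0.0735 against 0.1004). With array weights it was 0.558 (0.477 to 0.670) against 0.331, and the covariance 0.0819 against 0.0199. Over the 10 arrays it was 0.525 (0.411 to 0.673) against 0.311, and the covariance 0.0785 against 0.0215. Of 100 splits of the arrays, 61 reached the 0.318 and 28 the 0.558 with array weights. The simulated arrays vary independently, while same-numbered arrays of control, ND-75, UQCR-14 and COX5B RNAi deviated together, so the simulated values are no secure measure of what unchanged groups would give. The 3 controls are too few to be divided between comparisons.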

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

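Tests on the scaling, on RNA quality, on the shift of 4 arrays, on the targeted genes and on y and Cyp6a17, except the search for a chromosome segment, were chosen only after the results were seen, as were the splits of the 10 arrays and those within numbers.

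Differences between RNAi groups, each tested with limma's F test over the 4 groups, singled out 11 probe sets. The changes are log2 and give the RNAi group with the highest change minus that with the lowest. Cyp4p2 was 4.74 higher in UQCR-14 than in ATPsynCf6 RNAi, and Cyp4p1 was 3.10 higher in UQCR-14 than in ND-75 RNAi. Zip102B was 3.75 higher in ATPsynCf6 than in UQCR-14 RNAi. In ND-75 RNAi, y was 4.30, Cyp6a17 4.24, 1634666_at 2.83 and CG43117 2.57 higher than in COX5B RNAi, and 1640448_x_at was 3.28 higher than in UQCR-14 RNAi. ATPsynCf6 RNAi exceeded COX5B RNAi by 3.00 for Pepck1, and ND-75 RNAi by 3.44 for Hsc70-2 and by 2.12 for CG18095. Signals in the lower group lay under the array medians for Cyp4p2, Cyp4p1, Cyp6a17, 1634666_at and 1640448_x_at, and in 2 of 3 arrays for Hsc70-2 and Zip102B, so these sizes are not exact. In each group all 3 arrays carried the direction for Cyp4p2, Cyp6a17 and y. For y, the pair ND-75 and COX5B RNAi was the only one that passed over 15 arrays.

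The first pattern weighed was that 0 to 7 probe sets were called per RNAi group over 15 arrays and 21 to 715 with array weights. The scaling of the deposited signals as the whole source is argued against, since quantile normalization left 3 calls in UQCR-14 RNAi. A strong 3' bias is argued against for the replicate 3 arrays of control, UQCR-14 and COX5B RNAi, whose highest actin ratio was 3.58 where 9 others reached 5.03, but not for COX5B RNAi 1 and ND-75 RNAi 3, at 20.1 or more. A term for the 4 replicate 3 arrays gave 9 calls in UQCR-14, 2 in COX5B and 9 in ATPsynCf6 RNAi. Array weights gave 462, 21 and 715. These counts argue against a shift shared by the 4 arrays as the whole source. COX5B RNAi 1 stayed unweighted in the fit with the term, and no fit joined the term with leaving it out. The shift as a large part of the source therefore stays open. A handling of single arrays that such a term does not describe, COX5B RNAi 1 included, was not tested, nor was any biological explanation.

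The second pattern was that UQCR-14 and ATPsynCf6 were not lower in the arrays labelled with their RNAi. A large fall hidden by the 5 arrays is argued against, since over the other 10 the 95% interval ended at -0.42 for UQCR-14 and -0.20 for ATPsynCf6, and smaller falls stay open. An exchange of labels with another RNAi group could be seen only if the RNAi lowered its transcript measurably. Over the 10 arrays the lowest value of either gene in another RNAi group was -0.10 and the lowest end of an interval -0.47. These values argue only against an exchange with a larger fall than that, and other exchanges stay open. In their own groups ND-75 and COX5B stood at -0.53 each over the 10 arrays. Cells of the whole nervous system that lack the driver may hide a loss in neurons, signals as high as those of UQCR-14 may respond little, and the RNAi may have spared the transcript; none of these was tested.

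The third pattern was the rise of y and Cyp6a17 in ND-75 RNAi. The 5 arrays are argued against, since over the other 10 both stayed called, the higher adjusted p being 0.00144 (y 1.50e-11 to 0.351 and Cyp6a17 8.52e-06 to 0.00746 over 17 alternatives). A chromosome segment of another origin that carries many called genes is argued against, since 78 pairs of called genes lay 6 to 100 genes apart, where random draws gave 59 to 94 with a mean of 75.2. A change over the neighbourhood of both genes is argued against, since 0 of 20 genes within 5 places of either were called over the 10 arrays (lowest adjusted p 0.232). A marker carried with the RNAi line, a variant of each gene in the line's background and a response to the loss of complex I may each be the source and were not tested, since the design has no other line against ND-75 and no control construct.

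Other splits of the same arrays were counted for each comparison. Each RNAi group against control has 10 splits, which cannot give a share under 0.05. Over 15 arrays the real count and the highest other were 7 and 0 in ND-75, 5 and 0 in UQCR-14, 0 and 0 in COX5B, and 2 and 0 in ATPsynCf6 RNAi, so that 1, 1, 10 and 1 splits gave as many. With array weights they were 162 and 7387, 462 and 8395, 21 and 7873, and 715 and 301, with 5, 6, 6 and 1 splits as large. For the lists they were 1 and 12, 7 and 16, 5 and 13, and 7 and 16, with 9, 9, 5 and 7 splits as large. In ND-75, UQCR-14 and COX5B RNAi same-numbered arrays deviated together with those of control. There 4 of the 10 splits part all 3 same-numbered pairs, as the real one does. The highest other of these was 0 in each over 15 arrays, 27, 1393 and 411 with array weights, and 3, 8 and 4 for the lists. The other 6 keep 2 pairs whole, and the highest counts, 7387, 8395 and 7873, were among them. Splits that called many times the real count point to a structure of the samples.

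For the mean of the 4 RNAi groups over 15 arrays, 2 of 100 splits called at least the real 5, and the other called 3330 with control 3, ND-75 RNAi 3 and UQCR-14 RNAi 3 held as controls, which follows the arrays set apart, and the fit with a term for the 4 arrays called 9. With array weights 36 of 100 splits reached the real 413 (highest other 9126), so chance was not excluded, and the splits again point to a structure of the samples. Over the 10 arrays 1 of 45 splits reached 323, and the highest other, 195, held ND-75 RNAi 1 and 2 as control. For probe sets in the same direction in all 4, the splits as large were 100 of 100 over 15 arrays (real 0, highest other 0), 17 of 100 with array weights (real 11, highest other 6469) and 1 of 45 over the 10 arrays (real 36, highest other 19, the same ND-75 RNAi pair). Chance was not excluded in the first 2. Most splits against control put arrays of several groups together, which adds differences between groups to the spread and keeps counts low, and only 6 of the 45, and the real 1 of the 100, held arrays of 1 group as control. The shares of 2 in 100 and 1 in 45 therefore leave chance open, and the count of 36 also rests on 1 COX5B RNAi array. The similarity of fold changes was reached in 61 of 100 splits over 15 arrays (real 0.318, highest other 0.904) and in 28 with array weights (real 0.558, highest other 0.953), so chance was not excluded.

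For differences among the RNAi groups over 15 arrays, 1 of 100 splits, the real one, reached 11 (highest other 6). Where labels were exchanged only among arrays of 1 number, 1 of 100 did (highest other 8), although the numbers were not shown to pair arrays. This argues against chance for the count as a whole. It does not single out probe sets, since mixed splits hold differences between groups in their spread and so keep counts low. With array weights 60 of 100 reached 281 (highest other 9042), and 56 of 100 within numbers (highest other 5789), so chance was not excluded there. In the 10 arrays 2 of 100 reached 455 (highest other 566), but within numbers 4 of 72 did (highest other 1423), and COX5B RNAi had 1 array, so chance was not excluded there. Pairs of RNAi groups differed at the real count or more in 6 of 100 splits over 15 arrays (real 11, highest other 870), 69 with array weights (real 468, highest other 9327) and 5 of 100 over the 10 arrays (real 747, highest other 1268), so chance was not excluded in any of them. Within numbers 1 of 100 (highest other 8), 62 of 100 (highest other 6666) and 8 of 72 splits (highest other 2135) were as large.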

How the results depend on the processing

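Leaving out 5 or 6 arrays, the term for 4 arrays and the pairs of settings with quantile normalization were chosen only after the results were seen. The other settings were chosen beforehand. Signal near background and 3 arrays per group limit all values. Camera takes no robust option and was not run with one, and fitting only the 2 groups compared was not run for results over several groups. Unless stated otherwise, the cause was not tested. Lists are given with camera's adjusted p.

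Among settings chosen beforehand, values of named genes kept direction and call in 2185 cases, gained the call in 110, lost it in 86 and turned in 4. Among added ones they kept both in 238, gained it in 313, lost it in 1 and turned in 0. Lists kept both in 640 and 70 cases, gained the call in 16 and 26, lost it in 79 and 48 and turned in 20 and 24. Cyp6a17, CG15784 (both ND-75 RNAi), Cyp4p2 (UQCR-14 RNAi) and Hsc70-2 (ATPsynCf6 RNAi) were called in all 17 settings that left out no single array in turn, with adjusted p up to 0.00746, 0.0175, 0.0381 and 0.0210. The change of Cyp6a17, whose control signals lay near background, ran from 3.05 to 7.23 over them. The call of y ended in 1 of 17, pseudocount 1 (adjusted p = 0.351; 1.50e-11 to 0.351), and those of CG5079 in 2 of 17 (up to 0.0682), Hsc70-2 in UQCR-14 RNAi in 1 (up to 0.0739), Cyp4p1 in 2 of 16 (up to 0.480) and CG43117 in 6 of 17 (up to 0.257). RFeSP was called in 13 of 16 in ND-75 RNAi and 10 of 16 in UQCR-14 RNAi (up to 0.412 and 0.755), and Zip102B in 9 of 17 (up to 0.815).

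The fold change of UQCR-14 turned from 0.15 to -0.21 with quantile normalization, -0.0729 with median centring, -0.13 with array weights, -0.0442 without the 5 arrays and -0.0442 without 6. It was -0.21 with quantile normalization and the term for 4 arrays, -0.28 with quantile normalization and weights, and -0.31 with quantile normalization without the 5. ATPsynCf6, at -0.001, became in the same order 0.0479, 0.0190, 0.0538, 0.0744, 0.0744, 0.107, 0.0796 and 0.0887, and 0.0991 with the term for 4 arrays alone. With 1 array left out they ran from -0.55 to 0.66 and from -0.0790 to 0.0911. COX5B, at -0.72, passed the test with quantile normalization and weights (-0.69, adjusted p = 0.00553; 0.00553 to 1.00 over its alternatives).

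Over 15 arrays the counts of called probe sets were 7 in ND-75, 5 in UQCR-14, 0 in COX5B and 2 in ATPsynCf6 RNAi, 5 for their mean, 0 for all 4, 11 in the F test and 11 over pairs. In that order, array weights gave 162, 462, 21, 715, 413, 11, 281 and 468. Without the 5 arrays they were 175, 475, 128, 333, 323, 36, 455 and 747, and without 6, 96, 953, 307, 530, 552, 43, 507 and 916. Quantile normalization with weights gave 426, 2165, 2433, 765, 1511, 145, 2699 and 3403, and without the 5 arrays 229, 600, 261, 402, 448, 51, 593 and 976. Quantile normalization with the term for 4 arrays gave 11, 15, 14, 11, 15, 2, 19 and 36. That term alone gave 9 in UQCR-14, 2 in COX5B, 9 in ATPsynCf6, 9 for the mean and 1 for all 4. The mean correlation of fold changes moved from 0.318 to 0.558 with weights, 0.525 without the 5, 0.548 without 6, 0.544 with quantile normalization and weights and 0.528 with quantile normalization without the 5.

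Smaller moves were 3 in UQCR-14 and 4 in ATPsynCf6 RNAi with quantile normalization, and 4 in ATPsynCf6 RNAi with median centring. Pseudocount 1 gave 3 in ND-75 RNAi, 7 in the F test and 6 over pairs, and pseudocount 64 gave 1 in COX5B RNAi and 1 for all 4. No filter gave 3 in UQCR-14 RNAi and 1 for the mean, a stricter filter 2 and no trend 3 in UQCR-14 RNAi. Fitting only the 2 groups compared gave 1 in UQCR-14 and 16 in ATPsynCf6 RNAi.

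The replicate number as a block gave 3 in UQCR-14 and 4 in ATPsynCf6 RNAi and 2 lists in ND-75 RNAi, and it ended the calls of RFeSP and Zip102B in UQCR-14 RNAi (adjusted p = 0.0513 each; 2.93e-07 to 0.755 and 3.34e-08 to 0.815 over their alternatives). In ND-75, UQCR-14 and COX5B RNAi it changed no other call of a named gene or described list over 15 arrays without weights. Calls made only with array weights or with several arrays left out were not tested with the block. Outside their group, 9 of 15 arrays correlated best with an array of their own number. ATPsynCf6 RNAi 3 correlated at -0.201 to -0.103 with the 4 replicate 3 arrays set apart.

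With 1 array left out, the counts ran from 4 to 16 in ND-75, 2 to 12 in UQCR-14, 0 to 1 in COX5B, 0 to 14 in ATPsynCf6 RNAi, 0 to 11 for the mean, 6 to 12 in the F test and 7 to 23 over pairs. The highest came without COX5B RNAi 1, except for COX5B RNAi (UQCR-14 RNAi 3). The mean correlation ran from 0.205 to 0.469, with 0.213 and 0.205 without UQCR-14 RNAi 1 and 2, 0.457 without UQCR-14 RNAi 3, and 0.452, 0.448 and 0.469 without control 1, 2 and 3. CG17816 in ATPsynCf6 RNAi ran from -0.96 to 0.0653 and Arc2 in COX5B RNAi from -0.31 to 1.66. Counts of lists ran from 1 to 11 in ND-75, 4 to 14 in UQCR-14, 1 to 6 in COX5B and 7 to 13 in ATPsynCf6 RNAi. In ND-75 RNAi they were 2 without ND-75 RNAi 1, ND-75 RNAi 2 or COX5B RNAi 3, 11 without ND-75 RNAi 3, and 5, 4 and 6 without control 1, 2 and 3. In UQCR-14 RNAi they were 14 without UQCR-14 RNAi 1 or 2, 4 without control 2 and 13 without control 3. In COX5B RNAi they were 2 without UQCR-14 RNAi 3 and 1 without COX5B RNAi 1, and in ATPsynCf6 RNAi 11 without UQCR-14 RNAi 3 and 13 without control 1 or 2.

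The counts of lists over 15 arrays were 1 in ND-75, 7 in UQCR-14, 5 in COX5B and 7 in ATPsynCf6 RNAi, and an estimated correlation gave 0, 0, 0 and 0. In ND-75 RNAi they were 0 without the filter, 2 with median centring, 2 with pseudocount 64, 2 with the term for 4 arrays, 3 with weights, 7 without the 5 arrays and 3 without 6. Quantile normalization gave 3 there with the term, 7 with weights and 7 without the 5. In UQCR-14 RNAi they were 3 with quantile normalization, alone or with the term. In COX5B RNAi they were 3 with weights, 3 with all probe sets of each gene, and, with quantile normalization, 9 with the term, 3 with weights and 3 without the 5. In ATPsynCf6 RNAi they were 11 with only the 2 groups, 11 with the term and 12 with quantile normalization and the term.

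Some lists turned. In ND-75 RNAi the glue genes had 0.0457 with weights, 0.427 without the 5 arrays, 0.000445 without 6, and with quantile normalization 0.0475 with weights and 0.469 without the 5 (0.000445 to 0.975 over its alternatives; 0.0293 to 0.823 with 1 array left out). In UQCR-14 RNAi the cytosolic ribosomal proteins had 0.930 with quantile normalization, 0.992 with it and the term, 0.775 with it and weights and 0.572 with it without the 5 (1.37e-18 to 0.993; 1.41e-11 to 0.750 with 1 array left out). The ecdysone genes there had 0.901 with all probe sets (0.00425 to 0.993; 0.0335 to 0.934 with 1 array left out). In COX5B RNAi the mitochondrial ribosomal proteins had 0.342 with weights (1.08e-05 to 0.975; 1.88e-07 to 0.945 with 1 array left out).

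In ATPsynCf6 RNAi the complex I genes had 0.745 without the 5 arrays, 0.671 without 6, 0.284 with the term, and with quantile normalization 0.251 with the term and 0.878 without the 5 (2.02e-05 to 0.878; 9.04e-06 to 0.998 with 1 array left out). The mitochondrial ribosomal proteins had 0.577 with weights, 0.0958, 0.0727 and 0.0684 without 5, without 6 and with the term, and with quantile normalization 0.000634 with the term, 0.259 with weights and 0.0196 without the 5 (1.44e-05 to 0.768; 2.86e-07 to 0.741 with 1 array left out). The cytosolic ribosomal proteins had 0.174 with weights, 0.00137, 0.00142 and 8.85e-14 without 5, without 6 and with the term, and with quantile normalization 0.263, 0.931 and 0.827 in the same order as before (8.85e-14 to 0.931; 6.65e-07 to 0.159 with 1 array left out). The glutathione S-transferases had 0.782 without the filter (0.000261 to 0.943; 0.00941 to 0.938 with 1 array left out), and the fat body genes ran from 0.00145 to 0.980 with 1 array left out.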

Other observations

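The values that follow come from the array-weighted fit, and their description was chosen only after the results were seen, as no comparison was planned for these genes. Neuronal and hormone genes changed singly while their lists were not called. The allatostatin gene AstC rose in UQCR-14 (1.02) and ATPsynCf6 RNAi (1.10), as did the synapsin gene Syn (1.23 and 1.15) and the clock gene Pdp1 (1.02 and 0.86). The cryptochrome gene cry rose in UQCR-14 RNAi (0.98). The gene nSyb, whose promoter drives the RNAi, fell in UQCR-14 RNAi (-0.95). In ATPsynCf6 RNAi the ecdysone response genes Sox14 (-0.97) and Hr4 (-0.78) fell and Hr3 rose (0.71), and the glutamate receptor GluRIA (-0.81) and the neuroblast gene erm (-0.85) fell. Over the 10 arrays cry (adjusted p = 0.0586), Hr4 (0.150), Hr3 (0.131) and GluRIA (0.0536) were not called in these groups.

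Stress and one-carbon genes also changed singly. The cell death gene grim rose in ND-75 (1.32), UQCR-14 (1.65) and ATPsynCf6 RNAi (1.02). The antioxidant regulator cnc fell in the same groups (-1.01, -0.79 and -0.66). Roe1, which serves mitochondrial chaperones, fell in ND-75 (-0.82) and UQCR-14 RNAi (-0.61). Gnmt (1.99) and Sam-S (0.43) of the methionine cycle rose in ATPsynCf6 RNAi, and Sam-S in UQCR-14 RNAi (0.79). Calls that ended over the 10 arrays were those of Gnmt (adjusted p = 0.0838) and Sam-S (0.111) in ATPsynCf6 RNAi and of Roe1 in UQCR-14 RNAi (0.0801). Drsl5, a relative of an antimicrobial peptide, rose in ND-75 RNAi (1.91). The gene y also rose in UQCR-14 (1.07) and ATPsynCf6 RNAi (0.85).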
